A study of Mus musculus with 8 samples.

How the data were processed

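Gene expression was measured by RNA sequencing in 8 libraries of mouse cells. Per the labels' protocols, RNA was extracted with Trizol and 1 ug of total RNA went into each library, made with an Illumina TruSeq RNA kit. The groups, taken from the sample titles, were mouse embryonic fibroblasts (MEF) of the OG2 strain, the same kind of cells infected with Sox2, Klf4, Oct4 and cMyc together with Flag, Msx2 or shMsx2 at day 4 and day 8, and R1 embryonic stem (ES) cells. Each of these 8 groups held 1 library, so no difference between single libraries has a replicate check. The labels give no hairpin without a target, and the Flag arm was used as the control of both other arms.

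Per the submitters' processing notes, Bowtie, RSEM and the mm10 build were used. Versions, settings, the annotation release and the normalisation step are not given in the sources used here. The deposited values, treated as a score, were whole-number normalised tag values for 10775 genes, each listed with a transcript and a locus per the file headers. They were not raw counts. The highest value, 15538, was held by 10 genes in every library, 25 different genes over the 8 libraries, and the values at the top 100 ranks were the same in all 8 libraries. At rank 1000 from the top the libraries lay between 720 and 725, and at rank 4000 between 212 and 216. A value therefore follows largely from a gene's rank within its library, as after a quantile-type step, and a shift shared by most genes would not show. In MEF the next value down was 7978, so a gene that moved across this step differed by close to 2-fold without any intermediate value. The sum of the values ran from 3435928 in ES cells to 3513668 in the library labelled shMsx2 at day 8, and medians ran from 141 to 145. Sequencing depth is therefore unknown, and no counting interval was computed. Every gene exceeded 30 in at least 2 libraries, and genes at 0 numbered 165 in MEF, 9 to 29 in the infected libraries and 225 in ES cells.

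Of the 21550 lines below each header, 10775 were blank and were passed over. Of the gene identifiers, 10749 (99.8%) were found in the reference table of names. Symbols were filled from it for 40 genes, of which 18 had been turned into dates and 22 had no symbol. Coordinates are those of the deposited loci.

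Values were analysed as log2(value + 10), so folds of low genes are understated. The 10702 genes with a mean of at least 20 over the 8 libraries were tested. For each pair of libraries a gene was counted at a log2 difference of at least 1 in size, a 2-fold difference. Genes past this limit on both days were compared with the number that independent lists would share. That number treats every gene as equally likely to pass, so it may be too small where low genes pass more often. The analysis plan also held a branch for raw counts, which was not used because the values were already normalised.

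An additive model with day and arm was fitted over the 6 infected libraries with limma (3.58.1, R 4.3.3, with a mean-variance trend), with 2 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The days stand in for replicates in it, so its p-values measure how far the arm differences agree between days and not a spread between cultures. The median residual SD was 0.115 on the log2 scale. Tested on simulated data for Msx2 against Flag over 10702 genes, it recovered 96% of 200 genes changed 2-fold and 100% of those changed 4-fold, with 13 and 7 false calls. With no gene changed it made 4 calls. The simulated noise was normal and additive, with the SDs that the model itself had estimated, so these rates may be better than in the real data.

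Before the data were examined, 26 gene lists were fixed: endogenous pluripotency, epithelial, mesenchymal, fibroblast extracellular matrix, smooth muscle contractile, BMP-responsive, TGF-beta-responsive, osteogenic, adipogenic, keratinocyte, trophoblast, primitive endoderm, primitive streak and mesoderm, neural, cell cycle, p53 and senescence, interferon-responsive, macrophage, endothelial, skeletal muscle, DNA methyltransferase and TET, glycolysis, oxidative phosphorylation, immediate early and control genes, and the delivered factors with Msx2. For lists with at least 5 tested members, the median log2 difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A percentile below 2 or above 98 was called outside the matched lists. These percentiles describe the libraries and are not p-values. Limma p-values of list members were also adjusted within each list alone. That adjustment does not cover the 26 lists together, so some calls over a list alone may arise without an effect. A count of members at an unadjusted p under 0.05 has to be read beside the share over all tested genes.

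The position of each infected library between MEF and ES cells was the median over genes at least 4-fold apart in those cells, with bootstrap intervals over genes from 2000 draws. Genes were named by a rule also fixed beforehand: Msx2 and the delivered factors, the 6 highest and 6 lowest genes per comparison whose higher library reached 100, the 6 highest and 6 lowest of those past 2-fold on both days, and up to 4 members per list. Predicted gene models, small RNAs, histone and mitochondrial genes were passed over. Some genes that this rule picks are not reported here, though they stay in the counts and list medians. Genes called by limma and named outside this rule were chosen after their values were seen. Lists of hypoxia-responsive and leukocyte genes were added later for the closing tests.

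Alternatives were median-of-ratios scaling, no filter or a minimum mean of 200, pseudocounts of 5 and 50, a 4-fold limit, limma without the trend, leaving out each library in turn, means in place of medians, and other limits for the positions. Counts without genes at 0 in an infected library, and without genes at the highest value, were added after seeing the data. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.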

Results

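RNA abundance was measured during the first 8 days of reprogramming of mouse embryonic fibroblasts (MEF) towards a pluripotent state, to ask how the homeobox transcription factor Msx2, a known effector of BMP signalling, affects the process. The 8 libraries, 1 per group, came from MEF, from MEF infected with Sox2, Klf4, Oct4 and cMyc together with Flag, Msx2 or shMsx2 at day 4 and day 8, and from R1 embryonic stem (ES) cells, a mouse line derived from the early embryo. Values are the submitters' normalised tag values for 10775 genes, and differences are on the log2(value + 10) scale. A value follows largely from a gene's rank within its library, so shifts shared by most genes cannot be seen. Sequencing depth is unknown, and because no group had replicates, differences between single libraries are given without p-values.

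Msx2 (ENSMUSG00000021469, mm10 chromosome 13, 53466884 to 53473074) was listed at 36 in MEF and 44 in ES cells. With delivered Msx2 it stood at 3510 at day 4 and 7974 at day 8, against 16 and 8 with Flag. In the libraries labelled shMsx2 it stood at 17 and 14, so Msx2 was not lower there than with Flag (log2 difference 0.05 at day 4 and 0.41 at day 8), at levels near the floor of the values. Every direction drawn below from the libraries labelled shMsx2 carries this limit, since a loss of Msx2 was not seen in them.

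The delivered reprogramming factors were high in every infected library. Pou5f1, which encodes Oct4, was listed at 2 in MEF, at 3290 to 3686 in the day 4 libraries and at 4656 to 5922 in the day 8 libraries, against 1868 in ES cells. Sox2 stood at 2 in MEF and between 1924 and 2634 after infection, and Klf4 at 136 in MEF and between 4224 and 7969. Myc reached the highest value, 15538, in all 6 infected libraries, against 357 in MEF and 11 in ES cells. Since Myc stands at the ceiling and Klf4 at 7969 in all 3 libraries of day 8, these values do not show equal delivery between the arms. Of the 5 genes of this list, limma called 1 (Msx2 itself) between Msx2 and Flag, both over all genes and adjusted over the list alone. The same list gave 0 calls for shMsx2 against Flag by limma, with 0 at an unadjusted p under 0.05. Its median differences were -0.05 and 0.00 for Msx2 against Flag, and 0.07 and 0.00 for the libraries labelled shMsx2, at days 4 and 8.

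**Figure D1:**
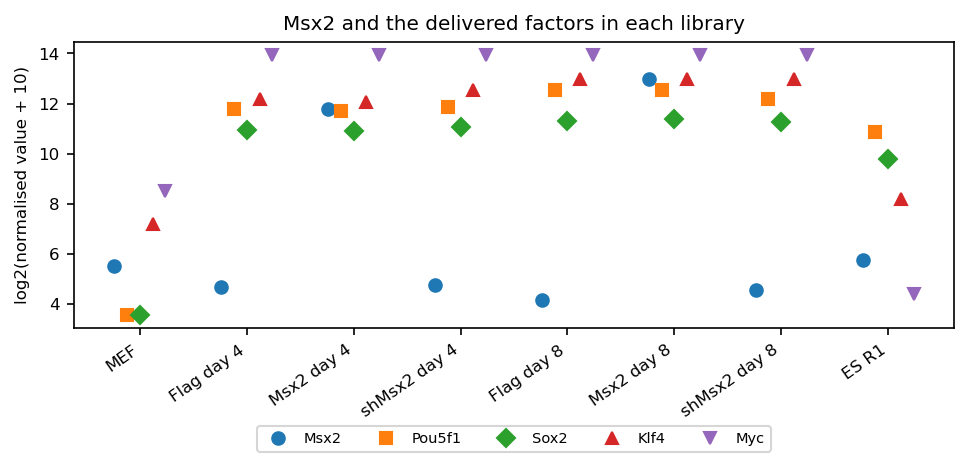
Normalised values of Msx2, Pou5f1, Sox2, Klf4 and Myc on the log2(value + 10) scale in each of the 8 libraries, 1 point per gene and library. Msx2 is high only in the 2 libraries that received it (3510 and 7974) and lies at 17 and 14 in those labelled shMsx2.

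With delivered Msx2, a small set of genes differed from Flag in the same direction on both days. The forkhead factor Foxd1 stood at 48 against 206 at day 4 and at 118 against 381 at day 8, and the interleukin-1 receptor antagonist Il1rn at 262 against 735 and 132 against 502. The thyrotropin receptor Tshr stood at 68 against 200 and 16 against 92, the zinc-finger repressor Bcl11a at 20 against 60 and 20 against 90, and the thyroid hormone binding protein Crym at 24 against 152 and 91 against 224. Higher with Msx2 were Lrmp (28 against 2, then 272 against 60), the ubiquitin ligase Sh3rf2 (99 against 36, then 286 against 107) and the transcriptional coactivator Cited1 (24 against 2, then 52 against 10). So were Ifi205 (36 against 9, then 33 against 8, with 32 in the day 8 library labelled shMsx2) and the embryonic globin Hbb-y (62 against 26, then 36 against 12). Tom1, an endosomal sorting protein, was listed at 0 in both Msx2 libraries against 120 and 92 with Flag, but also at 0 in MEF and in the day 4 library labelled shMsx2.

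In all, 9 genes, Msx2 itself included, were at least 2-fold higher and 18 at least 2-fold lower with Msx2 on both days. Independent lists would share 0.261 and 0.342. At a pseudocount of 50 these counts were 2 and 4, and at a minimum mean of 200 they were 1 and 2. The lower genes also included the transcription factors Ebf3 and Zic2 and the ecto-nucleotidase Nt5e. Some members have transcripts whose short sequence words largely occur in other genes too. This share was 100% for Gm3055, Gm5884 and Gm7334, 56.5% for Ifi205 and 81.7% for Tom1, against 0% for Hbb-y and 12.2% for Ms4a4b. Gm5884 and Gm7334 were listed at 0 with Flag on both days. Reads divided among near-identical copies may therefore account for part of these counts. The day 4 and day 8 differences, which share no library, correlated across genes at r = 0.312, and at 0.296 without Msx2 and genes listed at 0. Genes are not independent replicates. Only Pgk1-rs7 was higher at day 4 and lower at day 8, and only Gm17477 the reverse, against 0.277 and 0.322 for independent lists. Such lists treat every gene as equally likely to pass 2-fold, so all these expected numbers may be too small.

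The additive limma model over both days called 26 genes higher and 36 lower with Msx2 than with Flag (adjusted p under 0.05, 2 residual degrees of freedom), all 62 in the same direction on both days. Foxd1 fell by 1.75 ± 0.13 (log2 ± SE, adjusted p = 0.00124), Il1rn fell by 1.65 ± 0.12 (0.00124), Tshr fell by 1.70 ± 0.16 (0.0081) and Nt5e fell by 1.38 ± 0.14 (0.0105). Lrmp rose by 1.84 ± 0.19 and Sh3rf2 by 1.29 ± 0.14 (limma adjusted p = 0.0105 for both). Smaller rises were called for single genes, such as the fibrillar collagen Col1a2 by 0.45 ± 0.05, the basement membrane collagen Col4a1 by 0.40 ± 0.05, the collagen cross-linking enzyme Loxl2 by 0.50 ± 0.09 and the hemidesmosome collagen Col17a1 by 0.98 ± 0.15. The TGF-beta receptor Tgfbr2 rose by 0.68 ± 0.10 and the O-GlcNAc transferase Ogt by 0.63 ± 0.10. Id1, a direct target of BMP signalling, fell by 0.57 ± 0.10 (adjusted p = 0.0431), the retinoic acid degrading enzyme Cyp26b1 fell by 0.95 ± 0.15 and Tcf7l1, a repressor in the Wnt pathway, fell by 0.55 ± 0.09. Of the 9 and 18 genes past 2-fold on both days, limma called 3 and 14. It did not call Cited1, Ifi205, Hbb-y, Gm3055, Gm5884 and Gm7334 among the higher, nor Btg3, Tom1, Vav3 and Zic2 among the lower. Of all 10702 genes, 1309 had an unadjusted p under 0.05 in this limma model, the background for the list counts below.

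The counts of called genes depended on the set of libraries, the trend and the genes tested. Without Flag day 4 the model called 3 higher and 3 lower, without Flag day 8 it called 2 and 3, without Msx2 day 4 or Msx2 day 8 it called 3 and 10, and without either library labelled shMsx2 it called 0 and 0. Limma without the trend called 1 and 0 (1239 at an unadjusted p under 0.05), and a minimum mean of 200 left 3 and 4. Without genes at the highest value, a choice made after seeing the data, it called 42 and 58. With an arm reduced to 1 library, that library is assumed to vary like the other groups.

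**Figure D2:**
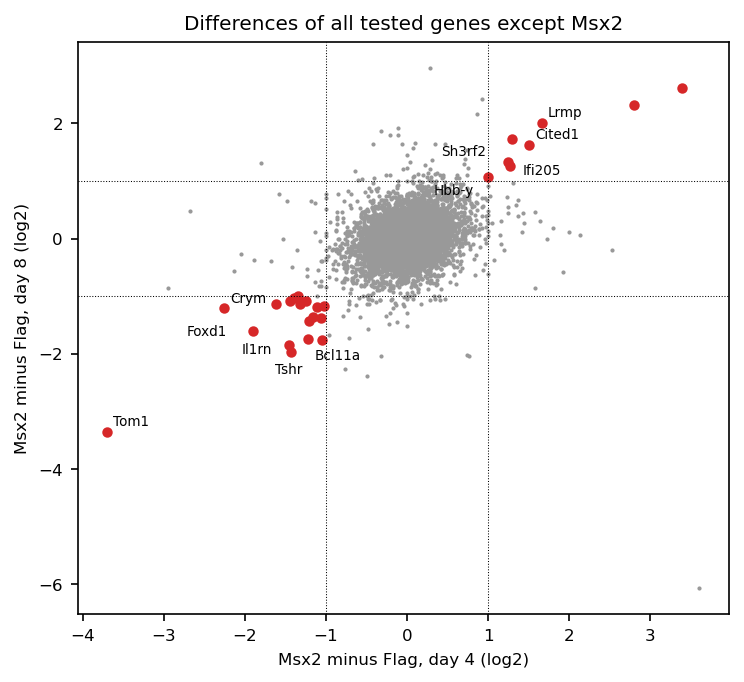
Log2 difference of each tested gene except Msx2 between the Msx2 and Flag libraries at day 4 (horizontal axis) and day 8 (vertical axis), 1 point per gene, with dotted lines at 2-fold. Red points are the genes past 2-fold in the same direction on both days, 8 higher here and 18 lower, with Tom1 the farthest below at -3.70 and -3.35.

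On single days, 43 genes were at least 2-fold higher and 53 lower with Msx2 than with Flag at day 4, and 65 and 69 at day 8. Day 4 examples higher with Msx2 were the kinase Prkcb (128 against 36), the epithelial cadherin Cdh1 (161 against 56), Cd34 (562 against 231) and Lrp4 (268 against 114). Lower were the pericyte-associated gene Rgs5 (97 against 432) and Osbp2 (31 against 121). Day 8 examples higher with Msx2 were Hif3a (110 against 23), Wnt5a (212 against 60) and the glutamate receptor subunit Grin1 (482 against 148). Lower were Enpp1 (86 against 309) and Galnt2 (111 against 320). Of the 2-fold genes, 10 of 43 and 9 of 53 at day 4, and 8 of 65 and 5 of 69 at day 8, were listed at 0 in the lower library. At a pseudocount of 50 the counts were 7 and 14 at day 4 and 12 and 17 at day 8, so most of these genes had low values.

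Among the fixed lists, cell cycle genes were lower with Msx2 on both days. Their median difference was -0.13 at day 4, where 19 of 24 members were lower, and -0.29 at day 8, where 21 were lower, at percentiles 0.01 and 0 of the matched lists. At day 8 the replication helicase genes Mcm5 (410 against 598) and Mcm2 (324 against 450) and the mitotic kinase Cdk1 (220 against 310) were examples. No member of this list passed limma over both days, over all genes or adjusted over the list alone (0 higher, 7 lower at an unadjusted p under 0.05). BMP-responsive genes had a median of -0.07 (percentile 22.0) at day 4 and -0.37 (percentile 0) at day 8, with Id3 at 56 against 102 and Smad9 at 47 against 84. Of the 13 members, limma called 1 lower over all genes, Id1, and 2 adjusted over the list alone, Id1 and Smad9.

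At day 8 the smooth muscle, matrix and epithelial lists were higher with Msx2. Smooth muscle contractile genes had a median of 0.35 (percentile 100), with the smooth muscle actin Acta2 at 3498 against 2520 and Myl9 at 202 against 148, while at day 4 the median was 0.08 (percentile 91.1). Extracellular matrix genes had medians of 0.00 at day 4 and 0.16 at day 8 (percentiles 49.8 and 99.99), with Col5a2 at 1996 against 1396 at day 8. Over both days limma called 2 of 25 matrix genes higher over all genes and 5 adjusted over the list alone (Col1a1, Fbln2, Col3a1, Col1a2 and Loxl2), and for smooth muscle genes 0 and 1, Acta2, with 5 of 12 higher at an unadjusted p under 0.05. Epithelial genes had medians of -0.13 (percentile 3.87) and 0.30 (percentile 99.94), with Spint1 at 142 against 72, the tight junction gene Lsr at 120 against 75 and Epcam at 403 against 274 at day 8. Limma called 0 of 19 epithelial genes in either adjustment (3 higher and 2 lower at an unadjusted p under 0.05).

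Keratinocyte genes went the other way at day 8, with a median of -0.49 (percentile 0.05). The keratins Krt17 (132 against 316), Krt14 (288 against 485) and Krt16 (78 against 134) were lower and Col17a1 (1047 against 628) higher, and the median was 0.01 (percentile 48.5) at day 4. With a minimum mean of 200 the day 8 median was -0.002. Limma called 1 of 8 higher over all genes, Col17a1, and adjusted over the list alone also 1 lower, Krt16.

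Primitive endoderm genes, of which 7 of 17 listed were tested, had medians of 0.36 (percentile 99.99) and 0.17 (percentile 96.7) with Msx2. Limma called 1 of 7 higher over all genes and 3 adjusted over the list alone, the basement membrane collagens Col4a1 and Col4a2 and the endocytic adaptor Dab2. Gata4, Sox17, Sox7 and Foxa2 were among the members without values. Gata6 lay near the floor, at 22 against 15 at day 4 and 4 against 3 at day 8. The tested members therefore cannot show whether cells moved towards primitive endoderm. The p53 and senescence list had medians of -0.01 (percentile 34.6) and 0.20 (percentile 99.97), with the cell cycle inhibitor Cdkn2a at 173 against 95 and the apoptosis gene Bbc3 at 207 against 130 at day 8. Limma called 1 of 16 higher over all genes, Trp53inp1, and adjusted over the list alone 4 higher (with Cdkn2a, Mdm2 and Cdkn2b) and 1 lower, Ccng1, whose difference is the step below the highest value (7977 against 15538 at day 4).

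Interferon-responsive genes had medians of 0.29 (percentile 99.64) at day 4 and -0.11 (percentile 14.4) at day 8 with Msx2, and immediate early genes -0.14 (percentile 2.13) and 0.18 (percentile 98.5). Glycolysis genes had medians of 0.04 (percentile 86.2) and 0.09 (percentile 98.9), the largest member difference being Pgk1 at 3928 against 1922 at day 8. Pgk1-rs7, which shares 100% of its short sequence words with other genes, was listed at 0 against 660 in that comparison. Whether reads were divided differently between it and Pgk1 was not tested. Endogenous pluripotency genes had medians of 0.21 (percentile 94.5) and -0.15 (percentile 11.7), with Nanog at 20 against 40 at day 8. Limma called 0 members of these 4 lists in either adjustment, with 0, 1, 3 and 1 at an unadjusted p under 0.05 in that order. Also inside the matched lists on both days were mesenchymal (0.00 and 0.02), TGF-beta-responsive (0.08 and 0.05), osteogenic (0.13 and 0.17), DNA methyltransferase and TET (0.07 and -0.08), oxidative phosphorylation (0.00 and 0.00) and control genes (0.00 and -0.01). Of these, limma called Prrx1 and Meox2 lower and Alpl higher adjusted over the list alone, and no member over all genes, with 3, 2, 2, 2, 0 and 0 members at an unadjusted p under 0.05 in the order given.

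Lists with fewer than 5 tested members were given no percentile. With Msx2 their medians at day 4 and day 8 were -0.08 and -0.07 for 3 adipogenic genes, 0.29 and 0.17 for 3 trophoblast genes, and 0.21 and 0.12 for 3 neural genes. They were -0.06 and 0.26 for 3 macrophage markers, 0.19 and 0.48 for 2 endothelial markers, -0.41 and 0.07 for 2 streak and mesoderm genes, and -0.52 and 0.22 for the 1 skeletal muscle marker, Acta1. The trophoblast regulator Tfap2c stood at 34 against 4 at day 8. Adjusted over the list alone, limma called Nes and Flt1 higher and Tubb3 lower, and none of these genes over all genes. With so few members, adjustment over the list alone corrects for little.

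**Figure D3:**
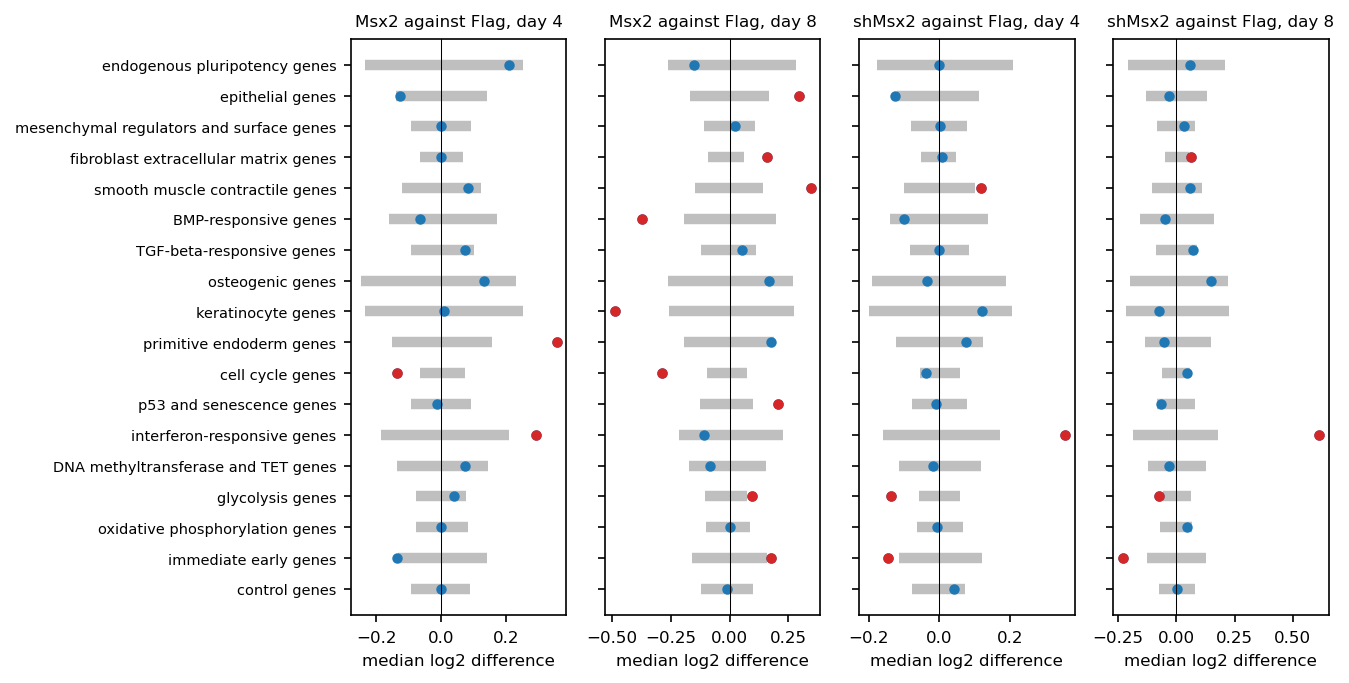
Median log2 difference from Flag of each gene list with at least 5 tested members (points), in 1 panel per comparison with its own horizontal scale, against the central 95% of 10000 matched random lists (grey bars). Red points lie outside percentiles 2 to 98, among them cell cycle genes with Msx2 on both days (-0.13 and -0.29) and interferon-responsive genes in the libraries labelled shMsx2 (0.35 and 0.61).

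In the libraries labelled shMsx2, in which Msx2 was not lower than with Flag, interferon-responsive genes stood apart at day 8. There the interferon regulatory factor Irf7 was listed at 62 against 17 with Flag, the antiviral genes Oasl2 at 165 against 64 and Oas2 at 346 against 159, the peptide transporter Tap1 at 102 against 36 and Irf1 at 144 against 58. The list's median was 0.61 at day 8 (percentile 100), where 12 of 13 members were higher and 5 were past 2-fold. At day 4 it was 0.35 (percentile 99.98), or 0.162 at a pseudocount of 50, and the Msx2 library stood nearly as high over the same Flag library (0.29). Msx2 against shMsx2 gave -0.07 (percentile 20.02) at day 4 and -0.72 (percentile 0) at day 8. The 3 genes at least 2-fold higher on both days, Zbp1 (34 against 5, then 74 against 18), H2-Q7 (40 against 11, then 51 against 18) and Irgm2 (16 against 0, then 85 against 36), encode a nucleic acid sensor, a class I histocompatibility molecule and an interferon-induced GTPase. The 3 tested macrophage markers had a median of 0.00 in the library labelled shMsx2 at day 8, against 0.27 at day 4. Lyz2 was listed at 0 both there and with Flag at day 8.

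Over both days limma called 0 genes higher and 0 lower for shMsx2 against Flag (377 at an unadjusted p under 0.05; without the trend also 0 and 0, with 483). Of the interferon-responsive genes 0 passed in either adjustment, with 6 of 13 higher at an unadjusted p under 0.05. Leaving out Flag day 4 or Flag day 8 gave 1 higher and 1 lower, and leaving out shMsx2 day 8 gave 2 and 2.

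On single days 24 genes were at least 2-fold higher and 18 lower than with Flag at day 4, and 37 and 17 at day 8. At a pseudocount of 50 these counts were 2 and 2, then 1 and 1, and at a minimum mean of 200 they were 0 and 1, then 1 and 1. The day 4 extremes included steps below the highest value, namely Ddx5 (15538 against 7962), Eef2, Hnrnpu, Atp5b, Gapdh and Ccng1, together with Btg3 (36 against 128), Rab8b (216 against 368), Ccdc102a (106 against 60), Stxbp2 (110 against 64) and Cml3 (112 against 68). At day 8 Irgm1 (134 against 58) was higher, and Col5a3 (36 against 104), Mamdc4 (42 against 106), Pcdh1 (56 against 112), Trp53inp2 (84 against 152) and Dst (4650 against 7962) were lower. On both days 3 genes were higher and 2 lower, Pgk1-rs7 (0 against 30, then 0 against 660) and Pydc3 (10 against 34, then 0 against 24), where independent lists would share 0.083 and 0.0286. The counts were 0 and 0 at a pseudocount of 50 and 0 and 1 at a minimum mean of 200. In opposite directions, 2 genes (2310031A07Rik and D130040H23Rik) were higher at day 4 and lower at day 8 and 1 (Pde1a) the reverse, against 0.0381 and 0.0622. The day 4 and day 8 differences correlated across genes at r = 0.0498.

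Glycolysis genes were lower in the libraries labelled shMsx2, with medians of -0.14 and -0.07 (percentiles 0 and 1.20), for example Pfkl at 304 against 373 at day 4 and Hk2 at 524 against 720 at day 8. Immediate early genes had medians of -0.15 and -0.23 (percentiles 0.7 and 0.03), with Fos at 32 against 56 and Egr1 at 279 against 404 at day 4 and 506 against 713 at day 8. Limma called 0 of either list over all genes and 1, Egr1, lower adjusted over the list alone (log2 difference -0.50 ± 0.10), with 1 gene of each list at an unadjusted p under 0.05. Smooth muscle genes had medians of 0.12 (percentile 98.9) and 0.06 (percentile 86.6), and matrix genes 0.01 (percentile 78.7) and 0.06 (percentile 98.5). The other lists with a percentile lay inside the matched lists on both days: pluripotency (0.00 and 0.06), epithelial (-0.13 and -0.03), mesenchymal (0.00 and 0.03), BMP-responsive (-0.10 and -0.05), TGF-beta-responsive (0.00 and 0.07), osteogenic (-0.04 and 0.15), and keratinocyte genes (0.12 and -0.07). So did primitive endoderm (0.08 and -0.05), cell cycle (-0.04 and 0.05), p53 and senescence (-0.01 and -0.06), DNA methyltransferase and TET (-0.02 and -0.03), oxidative phosphorylation (-0.01 and 0.04) and control genes (0.04 and 0.00). Smaller lists had medians of 0.09 and -0.14 (adipogenic), 0.00 and 0.10 (trophoblast), 0.04 and -0.01 (neural), 0.04 and 0.17 (endothelial), 0.12 and 0.08 (streak and mesoderm) and 0.12 and -0.08 (skeletal muscle).

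**Figure D4:**
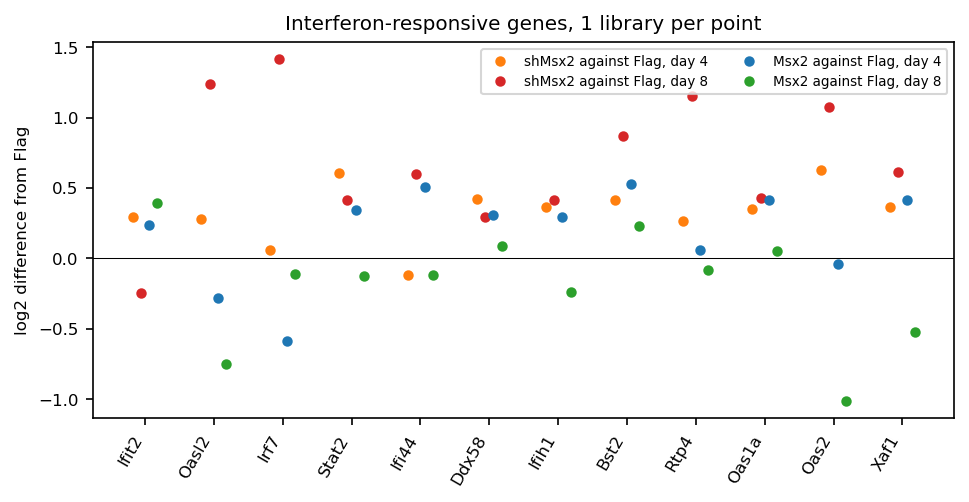
Log2 difference from the Flag library of the same day for tested interferon-responsive genes (horizontal axis), 1 point per gene and comparison. In the library labelled shMsx2 at day 8, every gene shown except Ifit2 lies above 0 and Irf7 reaches 1.42, while with Msx2 at day 8 Oas2 lies at -1.01.

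Set directly against the libraries labelled shMsx2, Msx2 gave 33 genes at least 2-fold higher and 48 lower at day 4, and 57 and 79 at day 8. Limma over both days called 29 higher and 37 lower, among them Msx2, Col1a2 and Col4a1. Of all 10702 genes, 1322 had an unadjusted p under 0.05 by limma. Adjusted over the list alone, the interferon-responsive genes Irf7, Oas2 and Oasl2 were lower with Msx2 than in the libraries labelled shMsx2 (log2 differences -1.08, -1.38 and -1.28) and the epithelial genes Krt19 and Cdh1 higher (0.69 and 1.02), with 0 of either list over all genes (5 and 3 at an unadjusted p under 0.05). Of the p53 and senescence genes, 5 were higher by the same adjustment (Cdkn2a, Mdm2, Cdkn2b, Trp53inp1 and Bbc3) and 1 lower (Igfbp3), with 0 over all genes. Other calls over the list alone were Col1a2, Loxl2, Col4a1, Col4a2, Col17a1, Acta2, Nes and Laptm5 higher and Krt16, Meox2, Id1 and Tubb3 lower. Cell cycle genes gave 0 calls by limma in either adjustment, with 10 of 24 lower at an unadjusted p under 0.05. Limma called 13 and 16 without Flag day 4, 11 and 18 without Flag day 8, 3 and 8 without Msx2 day 4, 3 and 11 without Msx2 day 8, 0 and 0 without shMsx2 day 4, and 2 and 2 without shMsx2 day 8. Without the trend it called 1 and 0 (1190 at an unadjusted p under 0.05), and with a minimum mean of 200 it called 1 and 1. Without genes at the highest value, it called 58 and 69.

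The differences of both arms from Flag were compared with each other. They correlated across genes at r = 0.439 at day 4 and 0.378 at day 8. Simulated unchanged arms gave 0.498 and 0.498 against the same Flag library. That value follows from giving both arms and Flag equal noise, so lying below it does not show whether the arms share effects. The covariance was 0.0308 and 0.0315, against simulated values of 0.0245 and 0.0244. Pairs that share no library correlated at 0.0016 (Msx2 day 4 with shMsx2 day 8) and 0.0613 (Msx2 day 8 with shMsx2 day 4). At day 4, 12 genes were 2-fold higher and 6 lower in both arms, including Cyp7b1, Irgm2, Btg3 and Tom1, and at day 8, 16 and 3, including Ifi205, Spry1, Pde1a and Pgk1-rs7 (chosen after their values were seen). Independent lists would share 0.0964 and 0.0891 at day 4 and 0.225 and 0.11 at day 8, and simulated unchanged arms shared 1.56 in each direction on average (at most 4 higher and 5 lower). Among the genes higher in both arms at day 4, Cyp7b1, Irgm2, Rex2, Spa17, Spock3, Gm5884, Gm7334, A630010A05Rik and D130040H23Rik were listed at 0 in Flag. At day 8 Nanp, Pfkfb1, Slc13a1, Thsd7b, Gm13242 and Gm6563 were listed at 0 in Flag. The simulated arms had normal noise and do not copy such zeros. With 1 Flag library per day the controls could not be split, so part of the excess may come from the shared control.

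Progress from the fibroblast towards the ES cell profile was placed on a scale from 0 (MEF) to 1 (ES cells). Over 641 genes at least 4-fold higher in ES cells, the median position was 0.363 with Flag, 0.358 with Msx2 and 0.357 in the library labelled shMsx2 at day 4, and 0.562, 0.556 and 0.557 at day 8. Over 981 genes at least 4-fold lower in ES cells, it was 0.266, 0.252 and 0.265 at day 4 and 0.345, 0.343 and 0.346 at day 8. Every gene listed exceeded 30 in at least 2 libraries, so genes above 30 only in ES cells are missing. The ES-high positions may therefore lie higher than they would with such genes. Genes above 30 only in MEF are missing too, so the ES-low positions may lie lower than they would with them. Every difference between an arm and Flag had a bootstrap interval over genes that included 0, for example -0.027 to 0.021 for Msx2 at day 4 and -0.033 to 0.026 at day 8 over the ES-high genes. At a pseudocount of 50 the first of these differences was 0.0343 in place of -0.004. Counts of single genes were less even: over the ES-high genes 336 were above and 270 below Flag with Msx2 at day 4, and 266 above and 350 below in the library labelled shMsx2 at day 8. Over the ES-low genes they were 418 and 530 with Msx2 at day 4 and 412 and 540 at day 8, and likewise 437 and 503, then 430 and 500, in the libraries labelled shMsx2, against the same Flag libraries. The intervals cover the choice of genes and not a spread between cultures.

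**Figure D5:**
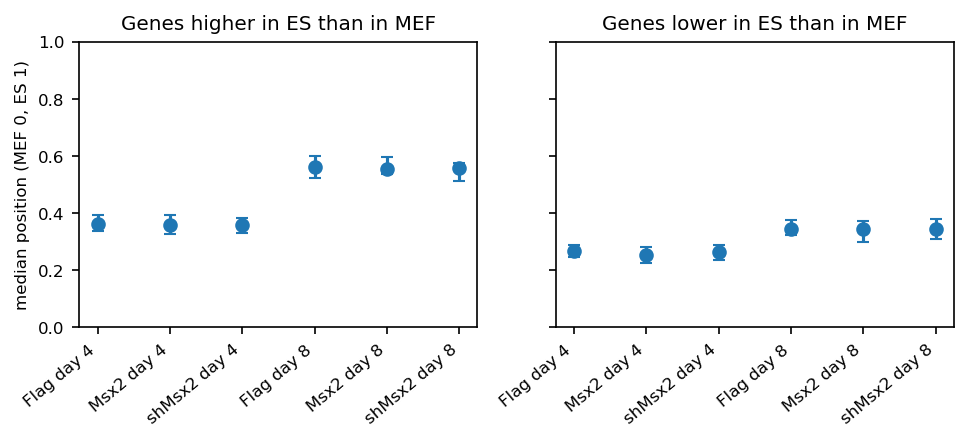
Median position of each infected library between MEF (0) and ES cells (1), over genes higher in ES cells (left, 641 genes) and lower in ES cells (right, 981 genes), with 95% bootstrap intervals over genes. The day 8 libraries lie at 0.556 to 0.562 on the left, and the arms overlap within each day.

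The infected control cells differed widely from MEF on both days, with epithelial genes higher and fibroblast genes lower. Flag cells at day 8 differed from MEF by at least 2-fold at 1741 genes higher and 1357 lower, against 1377 and 1025 at day 4. At a pseudocount of 50 the counts were 1078 and 864 at day 8 and 694 and 652 at day 4. Genes above 30 only in MEF are not among the 10775, which may reduce the counts of lower genes. Among the highest at day 8 were the desmosome component Dsp (3928 against 6), the hemidesmosome integrin Itgb4 (2867 against 4), Podxl (2634 against 8) and Nccrp1 (1414 against 0). Among the lowest were the macrophage lysozyme Lyz2 (0 against 2710), the cadherin Cdh3 (4 against 874), Wbscr17 (12 against 806), the interleukin-33 receptor Il1rl1 (24 against 1078), Lmod1 (6 against 495) and Svep1 (36 against 1298). Epithelial genes had a median of 3.13, with Krt8 at 891 against 2, and keratinocyte genes 4.92, with Krt14 at 485 and Krt17 at 316 where MEF were listed at 0. The 11 tested pluripotency genes, of 28 listed, had a median of 2.06, with 9 at least 2-fold higher and 2 at least 2-fold lower. L1td1 stood at 1636 against 2 and Tfcp2l1 at 111 against 5. Genes above 30 only in ES cells are not among the 10775, which may raise this median.

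Fibroblast programmes were lower in the same comparison of Flag day 8 with MEF. Matrix genes had a median of -2.42 (Postn 150 against 3298, Lox 470 against 5922), smooth muscle genes -2.77 (Tagln 376 against 3930), TGF-beta-responsive genes -1.82 (Itga11 72 against 962) and mesenchymal genes -1.07 (Pdgfra 52 against 810). Interferon-responsive genes had a median of -1.16 (Stat2 146 against 520) and primitive endoderm genes -0.86 (Gata6 3 against 48). Macrophage markers moved with these groups, at a median of -2.95, with Cd68 at 40 against 376 and Laptm5 at 102 against 519. Glycolysis genes had a median of 0.73 (Slc2a3 374 against 30) and DNA methyltransferase and TET genes 1.02 (Tet2 520 against 30). BMP-responsive (-0.01), cell cycle (0.03), p53 and senescence (0.37), osteogenic (0.07), immediate early (0.07) and control genes (0.33) lay inside the matched lists, as did oxidative phosphorylation genes (-0.30, percentile 2.91).

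ES cells differed from MEF at 2111 genes higher and 2279 lower. Highest were the laminin Lama1 (7978 against 13), Cdh1 (2712 against 4), Cmah (7970 against 32), Pou5f1 (1868 against 2), the glucose transporter Slc2a3 (5916 against 30) and the methylcytosine dioxygenase Tet1 (2432 against 10). Lowest were Lyz2 (0 against 2710), the matrix genes Col12a1 (25 against 15538), Col1a2 (40 against 15538), Bgn (49 against 15538) and Tnc (13 against 5926), and Acta2 (32 against 15538). All 11 tested pluripotency genes, of 28 listed, were higher, at a median of 4.88, and all 25 tested matrix genes lower, at a median of -7.11.

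From day 4 to day 8 the infected cells gained epithelial, pluripotency and glycolysis transcripts. Over the 3 arms limma called 2313 genes higher and 2897 lower at day 8 (6001 at an unadjusted p under 0.05). With median-of-ratios scaling it called 2659 and 2480, so which direction held more genes depended on the scaling. Epithelial genes rose in 17 of 19 cases, with 0 lower over all genes and 1, Cdh3, adjusted over the list alone. Epcam rose by 3.55 ± 0.17 (log2 ± SE), Krt8 by 3.34 ± 0.09 and Cdh1 by 2.25 ± 0.18. Of the 11 tested pluripotency genes, from a list of 28, 9 rose and 1, Tbx3, fell by either adjustment. Nanog was up by 1.75 ± 0.25 and L1td1 by 1.98 ± 0.07. The other listed members were not among the 10775 genes, so this covers only a part of the list. Keratinocyte genes rose in 7 of 8 cases (Krt17 by 3.95 ± 0.24) and interferon-responsive genes in 10 of 13, or 11 adjusted over the list alone (Oas2 by 2.10 ± 0.23). Glycolysis genes rose in 15 of 17 cases by either adjustment, with the glucose transporter Slc2a1 up by 3.42 ± 0.07. The oxygen sensor Egln3 rose by 4.09 ± 0.10, Aldoc by 4.96 ± 0.13 and Ndufa4l2 by 5.05 ± 0.13, in 3 of 3 arms each (chosen after their values were seen).

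Lower at day 8 were cell cycle genes, of which 18 of 24 fell and 1, Mki67, rose over all genes (19 and 1 adjusted over the list alone), with Mcm5 at -0.63 ± 0.10 and Plk1 at -0.56 ± 0.07. Smooth muscle genes fell in 10 of 12 cases with 1, Actg2, higher (Acta2 at -0.91 ± 0.05), mesenchymal genes in 12 of 22 with 5 higher (Prrx2 at -0.94 ± 0.11), and oxidative phosphorylation genes in 14 of 21, or 15 adjusted over the list alone (Cox4i1 at -0.32 ± 0.08). Matrix genes divided into 6 higher and 9 lower of 25 (Eln at 2.44 ± 0.17, Thbs2 at -0.88 ± 0.07). BMP-responsive genes divided into 3 and 6 of 13, TGF-beta-responsive genes into 6 and 5 of 16, and p53 and senescence genes into 3 and 7 of 16, the same numbers by either adjustment. Without shMsx2 day 4 the model called 1748 genes lower and without shMsx2 day 8 it called 1812. A minimum mean of 200 left 1058 higher and 1369 lower.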

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

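In this part, the tests on the interferon-responsive genes, on the low abundance and the shared-word subset of the genes at 0, and on the Flag library for hypoxia genes were chosen after the results were seen. The tests on shared words over all genes at 0 and on the slope were written before their values were seen. For both, the interval was brought into the reading after the values were seen.

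Pgk1-rs7 was the only result picked out by a difference between groups. It was higher with Msx2 than with Flag at day 4 (478 against 30) and listed at 0 against 660 at day 8, a difference of -9.675 between the log2 differences of the days. This difference was not tested, since each group holds 1 library. In the libraries labelled shMsx2 it was listed at 0 on both days, and in MEF and ES cells at 462 and 1378.

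Pgk1-rs7 belongs to 51 genes listed at 0 in one infected library and at 20 or more in another. Genes that share over 50% of their 31-base words with other genes were 11 of 50 among them and 14 of 253 among genes of like level (Fisher exact p = 0.000632). For that part, reads divided among near-identical copies may explain the zeros. Over the whole set, the median share of such words was 0.788 percentage points higher, under the 5 points set beforehand as speaking against copies, though its bootstrap interval (0.021 to 11.1) reaches past them. Of these genes, 52.941% (27 of 51; interval 38.5 to 67.1) reached 50 in an infected library, so neither copies nor low abundance could be settled as the cause of all, and no biological explanation was tested.

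Interferon-responsive genes stood higher in the library labelled shMsx2 than in Flag at day 8, by a median of 0.61. A low Flag library would raise the Msx2 library as well, but its median against the same Flag library was -0.111 (bootstrap interval -0.24 to 0.05). The Msx2 library may be low on its own account, so a low Flag library is not excluded. Macrophage RNA would bring Lyz2, which was listed at 0 in the day 8 library labelled shMsx2 and at 2710 in MEF. Lyz2 is itself among the 51 genes at 0 in one infected library and at 20 or more in another. Its zero therefore does not exclude macrophage RNA. Delivery of a hairpin remains possible: Msx2 itself was not lower (log2 difference 0.415), and no untargeted hairpin is in the design. The difference could therefore come from the hairpin, from loss of Msx2 below what these values resolve, from macrophage RNA, from a low Flag library or from the single culture.

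Hypoxia-responsive genes, an added list, stood higher with Msx2 than with Flag at day 8, by a median of 0.41 with 15 of 18 members higher (percentile 100), while at day 4 the median was 0.11 with 11 higher (percentile 98.8, bootstrap interval -0.19 to 0.16). At day 8 Vegfa was listed at 764 against 530, Ddit4 at 471 against 264 and Kdm3a at 1091 against 767. A low Flag library would raise the library labelled shMsx2 as well, but its median against Flag was -0.101 (percentile 0.85, 14 of 18 members lower). That library may be low on its own account, so a low Flag library is not excluded. Whether the Msx2 culture was further along the change from day 4 to day 8 stays open. Over all genes, Msx2 minus the library labelled shMsx2 at day 8 was set against Flag day 8 minus day 4. The slope was 0.054 (bootstrap interval 0.0397 to 0.0694). This lies between the limits set beforehand, at least 0.1 for this cause and below 0.05 against it. A lagging library labelled shMsx2 would give such a slope too, so it does not place Msx2 ahead of Flag. A Msx2 effect and a denser or less aerated single culture remain possible as well.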

How the results depend on the processing

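No named gene and no list median outside its matched lists changed sign, while some values near 0 did. Of 307 alternatives for named genes 278 kept their side of the limit and 29 fell below it. Of 504 for list medians 499 stayed inside the bootstrap interval of the reported median, which is wide for short lists, of 48 for positions 47 did, and of 272 for counts 161 stayed within 1.5 times. Scaling by library totals was not run, since it needs counts. Sequencing depth is unknown, so what it limits could not be computed. Except where fewer genes or libraries enter by construction, the cause of a move was not tested.

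Counts of 2-fold genes, higher and lower. With a minimum mean of 200: Msx2 against Flag 7 and 6 at day 4, 5 and 7 at day 8. For shMsx2 against Flag 0 and 1, then 1 and 1. For Flag day 4 against MEF 603 and 321, Flag day 8 against MEF 691 and 429, Flag day 8 against day 4 152 and 69, ES against MEF 828 and 910. On both days Msx2 1 and 2, shMsx2 0 and 1. With a pseudocount of 5: Msx2 day 4 67 higher, shMsx2 28 lower on either day. With a pseudocount of 50: Msx2 7 and 14 at day 4, 12 and 17 at day 8. For shMsx2 2 and 2, then 1 and 1. For Flag day 4 against MEF 694 and 652, Flag day 8 against MEF 1078 and 864, Flag day 8 against day 4 312 and 80. On both days Msx2 2 and 4, shMsx2 0 and 0. At 4-fold: Msx2 7 and 6 at day 4, 7 and 7 at day 8. For shMsx2 6 and 3, then 2 and 2. For Flag day 4 against MEF 329 and 244, Flag day 8 against MEF 597 and 367, Flag day 8 against day 4 149 and 24, ES against MEF 643 and 982. On both days Msx2 3 and 1, shMsx2 0 and 1. Without genes at 0 in an infected library (chosen after seeing the data): shMsx2 13 and 11 at day 4, 11 lower at day 8, 0 lower on both days.

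Limma counts, higher and lower. Without the trend: Msx2 against Flag 1 and 0, Msx2 against shMsx2 1 and 0. With a filter of 200: 3 and 4, 1 and 1, day 1058 and 1369. Without genes at the highest value (chosen after seeing the data): 42 and 58, 58 and 69. Leaving out 1 library at a time, where the lone library of an arm is assumed to vary like the others: Msx2 against Flag 0 to 3 higher and 0 to 10 lower, shMsx2 against Flag 0 to 2 and 0 to 2, Msx2 against shMsx2 0 to 13 and 0 to 18, day 1594 to 1851 and 1748 to 2116.

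List medians that left this interval were pluripotency genes with Msx2 at day 4 (0.103 at a pseudocount of 50), matrix genes in shMsx2 at day 4 (-0.026 as a mean), keratinocyte genes with Msx2 at day 8 (-0.002 at a minimum mean of 200) and interferon-responsive genes in shMsx2 at day 4 (0.609 at a minimum mean of 200, 0.162 at a pseudocount of 50). The position of ES-high genes, Msx2 minus Flag at day 4, was 0.0343 at a pseudocount of 50. The correlation of the arms was 0.271 (minimum mean of 200) and 0.0016 (no shared library) at day 4, and 0.348 (Spearman), 0.358 (minimum mean of 200) and 0.0613 (no shared library) at day 8.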

Other observations

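In this part, the tests on hypoxia genes between days and on leukocyte genes were written before their values were seen, and the test on splits of the libraries after. For the leukocyte genes, the interval was brought into the reading after the values were seen.

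From day 4 to day 8 the infected cells gained transcripts of oxygen sensing and glucose use. In Flag cells Egln3 stood at 102 and then 2333, Ndufa4l2 at 7 and then 642, and Aldoc at 4 and then 517. A hypoxia-type response was proposed, and hypoxia-responsive genes outside the glycolysis list were tested. Their median from day 4 to day 8 in Flag was 0.72, with 17 of 18 higher, at percentile 100 of matched lists, which fits such a response. The same list was also higher in ES cells than in MEF (median 0.945, 16 of 18 higher, percentile 99.91). A rise from day 4 to day 8 could therefore also go with movement towards the ES cell profile, and the test does not tell these apart. Crowding of the cultures may be a source too, but cell density was not measured here.

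Lyz2 was listed at 2710 in MEF and at 0 to 46 in the infected libraries. Fewer macrophages in the infected cultures could give this. Leukocyte genes outside the macrophage list had a median of -1.047 in Flag day 8 against MEF, with 5 of 6 lower (bootstrap interval -2.25 to 0.20), which meets the limits set beforehand for fewer macrophages (75% lower, a median of -1), but the interval includes 0. The explanation stays open.

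The genes limma called between days were set against other splits of the 6 libraries. Without an arm term the real split gave 4795 genes (5675 at an unadjusted p under 0.05), and only 1 of 10 splits, the real one, gave as many; the highest other split gave 0 (53 to 226 unadjusted). With 10 splits the share cannot fall under 0.05.

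Xist was listed at 210 in MEF, 2075 to 3934 in the infected libraries and 44 in ES cells, while the Y-linked Ddx3y stood at 151 to 196 and Uty at 98 to 134 in all 8. The imprinted gene H19 stood at 7970 in MEF, 758 to 1499 in the infected libraries and 5922 in ES cells. The surface marker Ly6a stood at 58 in MEF, 1135 to 1564 in the infected libraries and 2 in ES cells.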
